A study of Mus musculus with 18 samples.

How the data were processed

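Messenger RNA was measured in the iMGT-Myh6-eGFP line of mouse embryonic fibroblasts, which carries the reprogramming factors Mef2c, Gata4 and Tbx5 under control of doxycycline and a green fluorescent reporter driven by the cardiac gene Myh6. Per the labels' protocols, cells were plated at 1000 per well in 384-well plates and transfected with an siRNA against Chst7 or a control siRNA, and doxycycline at 1 µg/mL was given on the next day, named day 0. Day 0 samples received no doxycycline. The other samples were taken 1 and 3 days after its addition. Each sample pooled 40 wells, and the labels call the 3 samples of a group biological replicates. Libraries were prepared with a poly-A selection kit.

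The deposited table held whole-number read counts per gene, not normalized, for 24514 genes and 18 libraries. Per the submitters' processing notes, the authors used HISAT2, Subread, featureCounts and DESeq2 with the mouse build mm10. Their versions, the strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. The deposited counts therefore may split reads between near-identical genes in a way that is not known here, and counts of genes such as Prl2c2, Lce1g and Ifit3 are uncertain for that reason. Reads of a gene and of an overlapping or antisense gene cannot be told apart without the strand setting. Counts per gene also do not separate the delivered copies of Mef2c, Gata4 and Tbx5 from the cells' own. The 18 count columns were matched to samples by the library name in each sample's description, and the 1 other column held gene lengths. No mitochondrially encoded gene was among the listed genes, so that the list of such genes, a sign of RNA quality, had 0 members measured. In 25 rows the gene symbol had been turned into a date, and these rows were kept in the library totals and named nowhere.

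Gene symbols were matched to the RefSeq annotation of GRCm38, the assembly that mm10 also names, for coordinates, and 23591 (96.2%) matched. Gene lengths were those of the deposited table. Sequences of 3' untranslated regions (3' UTRs) came from the GENCODE annotation of the same assembly, by gene symbol. Coordinates are 1-based.

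Counts were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 for gene list tests. Genes were filtered with filterByExpr, which left 13802 genes, and libraries were scaled with TMM. All 18 libraries entered 1 quasi-likelihood fit with 6 groups and no covariate, which left 12 residual degrees of freedom. The common dispersion was 0.00331, a biological coefficient of variation of 5.75%. A gene was called where the edgeR quasi-likelihood F-test gave a Benjamini-Hochberg adjusted p below 0.05. The tests were two-sided. The comparisons were siChst7 against siControl at days 0, 1 and 3, siControl at days 1 and 3 against day 0, and the interaction terms that test whether the siChst7 effect at day 1 or day 3 differed from that at day 0. Log2 fold changes (log2FC) are from this fit. The value after the ± sign is a standard error worked back from the F-test, as the absolute log2FC over the square root of F. For genes near the floor in 1 group, such as Casq2 and Fabp3 at day 0, it can be too small, as the values without single libraries show. CPM values, counts relative to the size of the library, use the TMM-scaled totals and carry the standard deviation of 3 libraries.

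Gene lists were fixed with the design, before the data were examined, as were the tests, the rule for named genes and the alternatives except those said to have been added. There were 22 lists of pathways and gene classes and 9 lists of markers of other cell types or of RNA quality, 31 in all. Each list with at least 3 tested genes was tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test with an estimated correlation and the rotation test fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, and makes no comparison with other genes. Within each list, members called over all genes tested were counted, and so were members called with p-values adjusted over the list alone. Where a single pair of counts is given for a list, both ways gave the same counts.

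Named genes were Chst7, Mef2c, Gata4 and Tbx5, the 6 genes with the largest log2FC each way in each comparison of 2 groups, and up to 4 called members with the smallest p of lists that passed camera or had at least 3 called members. Genes with the largest log2FC had to be called, to have a mean of at least 5 CPM over all libraries and groups that did not overlap, and genes with symbols of predicted genes, clones or pseudogenes were left out. For the interaction terms the 4 largest each way were named. Uncalled members given as counterexamples were those with the highest mean CPM in their list, some of which are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

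Where 1 of the groups had no count, a fold change is given as a lower bound against 3 counts summed over the group. Where it had 1 to 3 counts, the ratio of CPM is given with its exact 95% counting interval. Such intervals cover counting error only, since reads copied by PCR are not independent molecules. A fitted log2FC of such a gene depends on the prior count and is no bound. Library totals ran from 30590742 to 50021142 counts, so that 3 counts in 1 library stand for 0.0600 to 0.0981 CPM.

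The siChst7 effect on genes changed over time was tested with camera on sets of genes called in siControl with at least a 2-fold change, each in a siChst7 comparison that shared no library with the one that defined the set. SiControl at day 3 against day 1 was fitted for this purpose. These camera p are unadjusted unless said otherwise. Overlaps of calls between days were compared with the product of the list sizes over the number of genes tested. Words of 6 bases in 3' UTRs were scored by regressing log2FC, limited to 2 either way, on the presence of each word in the 12587 tested genes (91.2%) with an annotated 3' UTR of at least 50 bases. The log2 length of the 3' UTR, its share of G and C bases, their squares and their product were first regressed out of both. Words held by fewer than 50 genes were left out. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for this step, and matplotlib 3.10.9 for figures.

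The test was checked on simulated counts with the totals of these libraries and 100 genes changed by each of 2 known folds. Each gene had a single mean and a single dispersion, taken over all libraries. For siChst7 against siControl at day 0 it recovered 90% of the genes changed 1.5-fold and 97% of those changed 2-fold, with 15 false calls among 13579 genes. At day 1 the shares were 86% and 95%, with 13 false calls among 13566 genes. At day 3 they were 86% and 97%, with 8 among 13583 genes. For the interaction with day 1 the shares were 73% and 91%, with 5 false calls among 13569 genes. For that with day 3 they were 74% and 89%, with 8 among 13585 genes. These simulated counts do not hold the wider spread between the real replicates of siChst7 at day 3. They also hold far fewer changed genes than were called in the real comparisons. The shares for day 3 and its interaction therefore do not show how the test performs on the real libraries of that group.

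Alternatives were DESeq2 1.42.0 size factors, library totals or upper quartile scaling in place of TMM, the DESeq2 Wald test, no filter, a filter of at least 50 counts in 3 libraries, only the libraries compared, the replicate number as a block, an adjusted p of 0.01, a test against a fold change of 1.2, and leaving out each library in turn. The removal of 2 siChst7 day 3 libraries together, and that of Chst7 from its list, were added after the data were seen. Uninduced cells at days 1 and 3 were not analysed here.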

Results

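The iMGT-Myh6-eGFP line of mouse embryonic fibroblasts converts toward cardiomyocyte-like cells once doxycycline switches on the transcription factors Mef2c, Gata4 and Tbx5. RNA was sequenced after transfection with an siRNA against Chst7 (siChst7) or a control siRNA (siControl), at day 0, just before doxycycline, and at days 1 and 3 of induction. Chst7 encodes a Golgi sulfotransferase that adds sulfate to glycosaminoglycans such as chondroitin. The series title sets the work in the question of how fibroblast identity is maintained during cardiac reprogramming. The design had 6 groups of 3 biological replicates, 18 libraries in all. Total counts per library ran from 44687733 to 46730986 in siControl and from 42829857 to 50021142 in siChst7 at day 0. At day 1 they were 34467618 to 36188373 and 39246932 to 44807490, and at day 3 they were 33129954 to 43905193 and 30590742 to 41435639. Of 24514 genes, 13802 were tested.

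Day of induction set most of the difference between libraries. The first principal component held 64.5% of the variance and placed day 0 libraries between -77.8 and -76.4, day 1 libraries between 10.1 and 16.3 and day 3 libraries between 60.7 and 64.5. The second held 14.8%. The third, with 4.47%, had siControl libraries at 5.8 to 24.4 and siChst7 libraries at -29.7 to -1. Libraries of a group differed by more than sampling noise in every group, with a chi-square per degree of freedom of 2.96 to 5.48 for most replicate pairs. The spread was wider in siChst7 at day 3, at 22.5 to 59.0, and for replicate 3 of siChst7 at day 0 against the other 2, at 15.2 and 15.5. In siChst7 at day 3, replicate 2 lay at -6.3 on the third component against -24 and -29.7 for the others. Rn45s, the ribosomal RNA precursor that poly-A selection should remove, took 1.96% of the counts of replicate 1 of that group, against 0.131% to 0.654% in the other 17 libraries. Replicates 2 and 3 of that group, at 0.605% and 0.654%, also lay above siControl at day 3, at 0.399% to 0.542%. The siControl mean itself rose from 0.147% at day 0 to 0.46% at day 3. Long and short genes also parted in siChst7 at day 3. Across genes, the rank correlation between gene length and the difference from siControl of the same day was -0.31, -0.26 and -0.33 in its 3 libraries. It was -0.05 to 0.03 in siControl at day 3, but those libraries belong to the reference group itself and are no baseline. In siChst7 at day 1 it was -0.13, -0.01 and -0.08. The trend ran the other way in replicate 3 of siChst7 at day 0, at 0.21 against -0.05 and -0.04 in the other 2 libraries of its group.

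Chst7 (chromosome X, 20058963 to 20099991, GRCm38) was low in every siChst7 library. At day 0 it had 19.7, 18.6 and 19.2 CPM in the siControl libraries and 0.238, 0.611 and 0.465 CPM with siChst7, or 2.29% of the control mean. At day 1 the values were 40.4, 37.2 and 35.3 against 0.95, 0.581 and 0.733 CPM (2.01%), and at day 3 they were 25.6, 23.8 and 25.9 against 2.96, 1.87 and 1.64 CPM (8.59%). The log2FC was -5.47 ± 0.18 at day 0 (edgeR adjusted p = 6.03e-15), -5.65 ± 0.17 at day 1 (edgeR adjusted p = 8.77e-16) and -3.54 ± 0.15 at day 3 (edgeR adjusted p = 7.07e-13). In siControl cells Chst7 itself was higher at day 1 than at day 0, with a log2FC of 0.97 ± 0.11, and at day 3, with 0.39 ± 0.11.

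**Figure D1:**
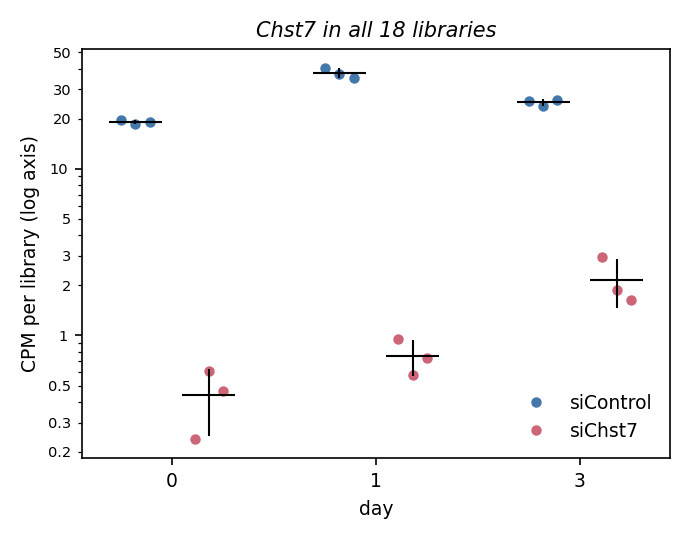
Chst7 in each of the 18 libraries, in CPM on a log axis, by siRNA and day (points are libraries). The siControl libraries lie between 18.6 and 40.4 and the siChst7 libraries between 0.238 and 2.96.

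In siControl cells the delivered factors and genes of the heart muscle sarcomere were higher after 1 day of induction than at day 0. Chemokine and matrix protease genes were lower (n = 3 libraries each). Mef2c (chromosome 13, 83504017 to 83667079) went from 47.1 ± 1.99 to 523 ± 8.53 CPM, a log2FC of 3.47 ± 0.05. Gata4 (chromosome 14, 63198914 to 63271712) rose by 3.16 ± 0.06 and Tbx5 (chromosome 5, 119796514 to 119885220) by 3.16 ± 0.05. These are sums over the delivered and the cells' own copies. Tnnt2 (chromosome 1, 135836315 to 135852268), the troponin T of heart muscle, went from 9.65 ± 0.641 to 86.2 ± 2.94 CPM. Ccl2, a chemokine that draws monocytes, went from 853 ± 50.5 to 20.5 ± 1.19 CPM.

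Of 26 sarcomere genes 21 rose and 0 fell at day 1, with a median log2FC of 3.01, or 2.82 with 7 genes near the floor set to their bound (camera adjusted p = 4.78e-22), among them Ldb3 (5.57 ± 0.09) and Myom2 (4.03 ± 0.08). All 3 delivered factors rose (camera adjusted p = 2.72e-26). Among the genes with the largest rises were the calcium store gene Casq2 (9.71 ± 0.19), which had 6 counts over the day 0 group, and Synpo2l (9.34 ± 0.14). Kcnc4 and Pdlim3 had 0 counts at day 0 and were at least 127-fold and at least 153-fold higher. Hspb7, whose 3' UTR holds the word GCGGCT, and Susd5 had 3 counts each at day 0, and their ratios were 783 (95% interval 268 to 3800) and 995 (340 to 4830). Their fitted log2FC moved from 9.43 to 10.25 without replicate 2 of siControl at day 0 and from 9.77 to 10.60 without replicate 3, while without replicate 1 Casq2 was at 10.63 and Fabp3, a fatty acid carrier gene of muscle, at 4.45. Of 11 smooth muscle markers 8 rose and 1 fell (camera adjusted p = 0.000112), led by Mylk (3.34 ± 0.10) and Des (2.58 ± 0.10), genes that heart muscle also expresses. Of 23 cholesterol synthesis genes 21 rose and 0 fell, with a median of 1.09 (camera adjusted p = 7.38e-16), such as Idi1 (2.42 ± 0.09) and Cyp51 (2.21 ± 0.05). Fatty acid oxidation genes rose in 13 of 23 cases and fell in 2 (camera adjusted p = 0.000821), with Fabp3 at 3.83 ± 0.24. These 5 lists also passed with an estimated correlation. Of 24 p53 and senescence genes 16 rose and 1 fell (camera adjusted p = 6.32e-05; adjusted p = 0.0571 with an estimated correlation), for example Btg2 (1.68 ± 0.04).

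All 27 called members of the 30 inflammatory genes fell at day 1, with a median of -2.05 (camera adjusted p = 4.66e-33; adjusted p = 1.78e-06 with an estimated correlation). Cxcl5 was at -9.30 ± 0.12, Ccl2 at -5.38 ± 0.14, Mmp3 at -4.73 ± 0.07 and Mmp13 at -4.59 ± 0.10. Outside that list the interleukin receptor gene Il1rl1 fell by 5.83 ± 0.09 and Ccbe1 fell by 5.34 ± 0.11. Of 34 interferon response genes 31 fell and 0 rose, or 31 and 1 when adjusted over the list alone (camera adjusted p = 1.06e-07; adjusted p = 0.099 with an estimated correlation), with Cxcl10 at -5.26 ± 0.23 and Rsad2 at -2.24 ± 0.13. Fibroblast identity genes fell in 20 of 27 cases and rose in 5, or 21 and 5 adjusted over the list alone (camera adjusted p = 3.19e-05; adjusted p = 0.0581 with an estimated correlation). They included the proteoglycan Dcn (-2.02 ± 0.11) and the transcription factors Bnc1 (-2.30 ± 0.08) and Osr1 (-2.08 ± 0.10), whose 3' UTR holds GCGGCT, while the fibroblast filament gene Vim was higher (1.25 ± 0.04). Of 30 matrix genes 20 fell and 8 rose (camera adjusted p = 0.000567; adjusted p = 0.34 with an estimated correlation), from Igfbp4 at -2.93 ± 0.08 to Col12a1 at 1.74 ± 0.06. AP-1 and immediate early genes fell in 12 of 19 cases and rose in 4 (camera adjusted p = 0.00135; adjusted p = 0.135 with an estimated correlation), including Fosl1 (-2.43 ± 0.08) and Jun (-2.16 ± 0.05). Of 22 proteoglycan core genes 12 fell and 6 rose (camera adjusted p = 0.0025; adjusted p = 0.077 with an estimated correlation). Markers of adipocytes fell in 5 of 6 cases, 1 rising (camera adjusted p = 0.0189, and 0.0633 with an estimated correlation). Macrophage and leukocyte markers were not called as a list by camera, but of these 7 genes DESeq2 called 5 lower and 1 higher, with a median log2FC of -1.97.

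In all, edgeR called 8322 of 13802 genes at day 1 against day 0, 4071 higher and 4251 lower, 979 and 935 of them by at least 2-fold. The groups did not overlap in 9536 genes (69.1%), where chance gives 10%. No uninduced cells were followed to day 1 or day 3 here, so the effects of the factors, of time in culture and of time since transfection were not separated.

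By day 3 the sarcomere programme of siControl cells was far higher and the inflammatory genes lower still against day 0 (n = 3 each). Tnnt2 reached 680 ± 24.8 CPM, a log2FC of 6.14 ± 0.09, and 25 of 26 sarcomere genes rose with 0 falling and a median of 6.13, or 5.95 at the bounds (camera adjusted p = 3.7e-40). Actc1, the cardiac actin gene, had 2 counts at day 0 and 105 ± 8.74 CPM at day 3, a ratio of 6970 (95% interval 1930 to 57500), and its fitted log2FC moved from 12.50 to 15.05 without replicate 1 of siControl at day 0. Pdlim3, Kcnc4 and Mybph had 0 counts at day 0 and were at least 1350-fold, 765-fold and 682-fold higher. Mef2c stood at 322 ± 3.43 CPM, with a log2FC of 2.77 ± 0.05, Gata4 at 2.49 ± 0.05 and Tbx5 at 2.44 ± 0.05, and all 3 delivered factors rose as a list (camera adjusted p = 4.89e-12).

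Smooth muscle markers rose in 9 of 11 cases and fell in 1 by day 3 (camera adjusted p = 8.7e-10), and p53 and senescence genes rose in 22 of 24 and fell in 1, with a median of 1.38 (camera adjusted p = 1.45e-12). The cell cycle inhibitor Cdkn1a rose by 2.02 ± 0.05. Cell cycle genes fell in 27 of 34 cases and rose in 5 (camera adjusted p = 7.92e-06), such as Mki67 (-1.57 ± 0.05) and Foxm1 (-1.53 ± 0.05). Fatty acid oxidation genes rose in 17 of 23 cases and fell in 4 (camera adjusted p = 0.000722), with Fabp3 at 5.99 ± 0.20 and Acaa2 at 1.99 ± 0.05. Of 30 inflammatory genes 28 fell and 1 rose, with a median of -3.09 (camera adjusted p = 2.6e-32), with Cxcl5 at -12.17 ± 0.15 and Ptgs2, a prostaglandin synthase gene, at -3.29 ± 0.06. Each of these lists passed with an estimated correlation as well. Of 16 ion handling genes 7 rose and 6 fell, with a median of 0.28 (camera adjusted p = 0.00299; adjusted p = 0.0197 with an estimated correlation), a call lost without the filter on low counts (camera adjusted p = 0.226). Casq2 (12.73 ± 0.16) and the junction gene Jph2 (8.26 ± 0.12) were among the 7, and the potassium channel gene Kcnj2 fell (-1.61 ± 0.10). Without replicate 1 of siControl at day 0 Casq2 was at 13.65 and Fabp3 at 6.61.

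Interferon genes fell in 29 of 34 cases and rose in 2 by day 3 (camera adjusted p = 1.14e-06; adjusted p = 0.158 with an estimated correlation), and fibroblast identity genes fell in 22 of 27 and rose in 1 (camera adjusted p = 1.54e-05; adjusted p = 0.0511 with an estimated correlation). Dcn fell by 4.44 ± 0.13. Of 19 AP-1 and immediate early genes 15 fell and 4 rose (camera adjusted p = 2.04e-05; adjusted p = 0.0582 with an estimated correlation), with Fosl1 at -3.40 ± 0.09. Cholesterol synthesis genes rose in 20 of 23 cases and fell in 1 (camera adjusted p = 2.14e-06; adjusted p = 0.125 with an estimated correlation). Matrix genes were divided, with 12 higher and 12 lower of 30, or 12 and 13 adjusted over the list alone, and their median of -0.02, mean of -0.07 and upward test differed in sign (camera adjusted p = 0.925).

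At day 3 against day 0 edgeR called 10132 genes in all, 4680 higher and 5452 lower, 1725 and 1298 by at least 2-fold. Scaling by library totals alone moved the share of higher genes from 46.2% to 57.8% and the median log2FC of all genes from -0.05 to 0.10. The share was 51.6% with DESeq2 size factors, 53.6% with upper quartile scaling, 50.1% with no filter and 51% with the stricter filter. With only the compared libraries it was 51.1%. Small changes thus depend on the scaling and the filter.

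At day 0, before doxycycline, siChst7 cells had less contractile actin and fewer transcripts of the TGF-beta response than siControl cells (n = 3 each). Acta2 (chromosome 19, 34240336 to 34255585), the smooth muscle actin that marks myofibroblasts, was 1290 ± 69.9 CPM in siControl and 468 ± 30.2 CPM with siChst7, a log2FC of -1.47 ± 0.06 (edgeR adjusted p = 1.81e-13). Tagln, another actin-binding myofibroblast marker, fell from 226 ± 11.9 to 92.4 ± 5.16 CPM, and the growth factor gene Tgfb2 had a log2FC of -1.29 ± 0.06. Of 25 myofibroblast and TGF-beta genes 11 fell and 5 rose, or 13 and 6 adjusted over the list alone (camera adjusted p = 2.62e-17; adjusted p = 0.00789 with an estimated correlation). Uncalled members included Pmepa1 (0.08 ± 0.05), whose 3' UTR holds GCGGCT.

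Of 26 glycolysis and hypoxia genes 16 fell and 1 rose, or 17 and 1 adjusted over the list alone, at day 0, with a median of -0.31 (camera adjusted p = 7.2e-11; adjusted p = 0.0365 with an estimated correlation). Pfkl (-0.73 ± 0.05) and Eno3 (-0.66 ± 0.04), both glycolytic enzymes, fell, and the abundant pyruvate kinase gene Pkm did not pass (0.01 ± 0.06). Unfolded protein and integrated stress genes fell in 13 of 28 cases and rose in 3 (camera adjusted p = 0.00501; adjusted p = 0.0728 with an estimated correlation), such as the stress regulators Atf4 (-0.49 ± 0.04) and Trib3 (-0.74 ± 0.08). Of 11 smooth muscle markers 5 fell and 0 rose, or 6 and 3 adjusted over the list alone and 5 and 2 by DESeq2 (camera adjusted p = 0.0069; adjusted p = 0.0658 with an estimated correlation), with Actg2 at -1.99 ± 0.12 and Lmod1 at -1.34 ± 0.20. Cholesterol synthesis genes rose in 9 of 23 cases and fell in 0, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.00344; adjusted p = 0.463 with an estimated correlation), for example Hmgcs1 (0.47 ± 0.06). Inflammatory genes rose in 8 of 30 cases and fell in 2, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0375; adjusted p = 0.104 with an estimated correlation). Mmp13 (0.82 ± 0.08) and Mmp3 (0.75 ± 0.06) were higher. Ccl2, at 0.19 ± 0.11, was called only without the filter, with library totals or with the compared libraries alone (edgeR adjusted p = 0.000659, 0.0474 and 0.00788). Without replicate 1 of siControl at day 0 the inflammatory and smooth muscle lists no longer passed (camera adjusted p = 0.0891 and 0.0693), nor did the smooth muscle list without the filter on low counts (camera adjusted p = 0.11).

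Tnnt2 was already higher with siChst7 at day 0, at 20.8 ± 0.609 against 9.65 ± 0.641 CPM (1.11 ± 0.08), while 2 of 26 sarcomere genes fell and 1 rose (camera adjusted p = 0.73). The delivered factors were near their control levels, Mef2c at 0.00 ± 0.05 (edgeR adjusted p = 0.993), Gata4 at -0.13 ± 0.05 (edgeR adjusted p = 0.074) and Tbx5 at -0.13 ± 0.05 (edgeR adjusted p = 0.0495). The call for Tbx5 was lost without replicate 1 or 2 of either day 0 group (edgeR adjusted p = 0.122 to 0.222). It was also lost under every other scaling and filter, under the block and with only the compared libraries (edgeR adjusted p = 0.0568 to 0.359), and with the DESeq2 test (adjusted p = 0.0534). Gata4 was called without replicate 3 of siChst7 at day 0 (edgeR adjusted p = 0.0129). Of 18 cardiac transcription factor and secreted factor genes 8 fell and 4 rose (camera adjusted p = 0.132), with Ankrd1 at -0.80 ± 0.05, Srf at -0.63 ± 0.05 and Ppargc1a at 1.49 ± 0.12. The growth factor receptors Pdgfra (0.91 ± 0.05) and Pdgfrb (0.81 ± 0.04), markers of fibroblasts, rose, while the identity list was divided, with 6 higher and 8 lower of 27, or 7 and 9 adjusted over the list alone (camera adjusted p = 0.652). Interferon genes numbered 2 higher and 5 lower of 34, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.455), with Isg15 at -0.49 ± 0.09. Other large changes included Fam180a (1.87 ± 0.23), Prl2c2 (1.77 ± 0.11), Ptprv (1.71 ± 0.20), annotated as a transcribed pseudogene, and Nrep (1.65 ± 0.08), and Sync (-1.56 ± 0.12) and Fhl1 (-1.53 ± 0.07), whose 3' UTR holds GCGGCT.

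EdgeR called 3785 genes in all at day 0, or 27.4%, 1916 higher and 1869 lower, 142 and 75 by at least 2-fold. The groups did not overlap in 6009 genes (43.5%), where chance gives 10%. With library totals as the only scaling, 69.4% of the called genes were higher in place of 50.6%.

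After 1 day of induction the siChst7 cells had higher levels of interferon and inflammatory genes than siControl cells (n = 3 each). Cxcl10 (chromosome 5, 92346638 to 92348889), an interferon-induced chemokine, was 3.69 ± 0.847 CPM with siChst7 and 1.04 ± 0.467 CPM in siControl, a log2FC of 1.82 ± 0.29, and Ccl2 was 43 ± 1.83 against 20.5 ± 1.19 CPM. Of 34 interferon genes 23 rose and 0 fell, or 26 and 0 adjusted over the list alone, with a median of 0.42 (camera adjusted p = 2.34e-12; adjusted p = 0.107 with an estimated correlation). They included Rsad2 (1.11 ± 0.13), Ifit1 (0.69 ± 0.11) and Oasl1 (0.92 ± 0.15), whose 3' UTR holds GCGGCT. B2m (0.10 ± 0.12) was called only with the compared libraries alone in the fit (edgeR adjusted p = 0.0136). Inflammatory genes rose in 14 of 30 cases and fell in 2, or 17 and 2 adjusted over the list alone, with a median of 0.39, or 0.33 with 2 genes at their bound (camera adjusted p = 1.7e-12; adjusted p = 0.0002 with an estimated correlation). Mmp13 (1.26 ± 0.11), Mmp3 (1.08 ± 0.07), Ptgs2 (0.66 ± 0.06) and the complement gene C3 (0.56 ± 0.05) were among them. Of 7 macrophage and leukocyte markers 3 rose and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.146), and the most abundant of them, Cd14, had a log2FC of 0.37 ± 0.09, a call lost without replicate 1 of siControl (edgeR adjusted p = 0.0612).

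The collagen genes Col6a3 (0.76 ± 0.09) and Col1a2 (0.52 ± 0.05) were higher at day 1. Of 30 matrix genes 11 rose and 1 fell, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.00251; adjusted p = 0.531 with an estimated correlation), and the abundant fibronectin gene Fn1 (-0.11 ± 0.05) was called only with the compared libraries alone in the fit (edgeR adjusted p = 7.51e-05). Smooth muscle markers fell in 4 of 11 cases and rose in 0, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.00015; adjusted p = 0.0185 with an estimated correlation), with Actg2 at -0.85 ± 0.11 and Mylk, whose 3' UTR holds GCGGCT, at -1.06 ± 0.08. Of 27 genes of glycosaminoglycan sulfation and chondroitin synthesis, Chst7 among them, 5 fell and 2 rose, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.000119; adjusted p = 0.198 with an estimated correlation). The call was lost when Chst7 itself, the target, was left out of the list (camera adjusted p = 0.211), an alternative added after the data were seen. The linker enzyme gene B4galt7, whose 3' UTR holds GCGGCT, was at -0.58 ± 0.07. Cholesterol synthesis genes rose in 6 of 23 cases and fell in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.0198; adjusted p = 0.556 with an estimated correlation). Glycolysis and hypoxia genes fell in 7 of 26 cases and rose in 4, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.0259; adjusted p = 0.472 with an estimated correlation). Of 7 endothelial markers 3 rose and 0 fell (camera adjusted p = 0.0259; adjusted p = 0.217 with an estimated correlation), Vwf from 2.68 ± 0.594 to 4.78 ± 0.809 CPM. Leaving out single libraries ended the cholesterol call (replicate 2 of siChst7, camera adjusted p = 0.182, and replicate 3 of siControl, 0.235). Leaving out replicate 1 of siControl ended those of the endothelial and glycolysis lists (camera adjusted p = 0.0907 and 0.0651), as did testing without the filter on low counts (camera adjusted p = 0.0965 and 0.0648).

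The sarcomere list was divided at day 1, with 4 higher and 4 lower of 26, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.717). Tnnt2 (0.36 ± 0.07) and Xirp1 (1.08 ± 0.10) rose, and Myom2 (-0.55 ± 0.07) and Myl4, whose 3' UTR holds GCGGCT, fell (-0.83 ± 0.14). Casq2 was 17.7 ± 2.12 against 40.3 ± 2.17 CPM. EdgeR and DESeq2 called 0 of the 3 delivered factors over all genes, while 2 were higher at an unadjusted p below 0.05 and 1 when adjusted over the list alone, with Mef2c at 0.13 ± 0.05 (edgeR adjusted p = 0.068), Gata4 at 0.09 ± 0.05 (edgeR adjusted p = 0.234) and Tbx5 at 0.10 ± 0.05 (edgeR adjusted p = 0.156). With only the libraries compared in the fit all 3 were higher (edgeR adjusted p = 0.00052, 0.0137 and 0.00247), and without the filter Mef2c was (edgeR adjusted p = 0.0428). Myofibroblast and TGF-beta genes rose in 6 of 25 cases and fell in 4, or 7 and 5 adjusted over the list alone, and their median of 0.02, mean of -0.08 and upward test differed in sign (camera adjusted p = 0.515). Among the genes that met the rule for naming, the largest fall after that of Chst7 was in Pip4k2c (chromosome 10, 127197067 to 127211628), a lipid kinase gene with GCGGCT in its 3' UTR, at -1.26 ± 0.05 (edgeR adjusted p = 2.27e-14). The splicing factor gene Prpf19, without that word, followed among the strongest at -1.15 ± 0.04, and the fatty acid oxidation enzyme gene Acadm, with it, was at -0.96 ± 0.06.

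In all, edgeR called 2426 genes at day 1, or 17.6%, 1223 higher and 1203 lower, 101 and 39 by at least 2-fold. The groups did not overlap in 5438 genes (39.4%), where chance gives 10%.

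**Figure D2:**
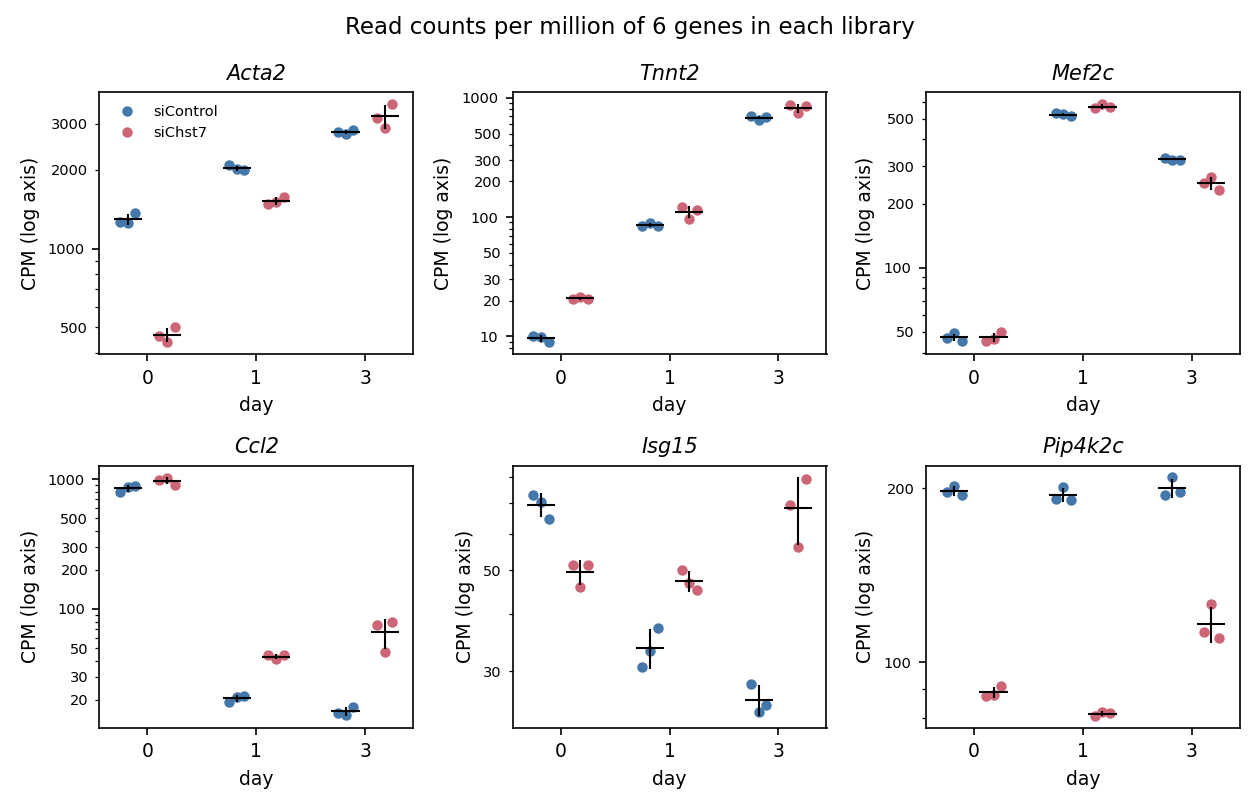
CPM of Acta2, Tnnt2, Mef2c, Ccl2, Isg15 and Pip4k2c by siRNA and day on log axes, with points for libraries, lines for means and bars for standard deviations (n = 3). Acta2 lies at 1290 in siControl and 468 with siChst7 at day 0, and Ccl2 at 16.3 and 66.8 at day 3.

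At day 3 the siChst7 cells had more interferon, chemokine and natriuretic peptide transcripts than siControl cells and less of the 3 delivered factors (n = 3 each). Isg15, an interferon-induced ubiquitin-like protein, was 68.2 ± 11.5 against 26 ± 2 CPM, and Ccl2 was 66.8 ± 17.3 against 16.3 ± 1.33 CPM. Of 34 interferon genes 28 rose and 1 fell, or 29 and 1 adjusted over the list alone, with a median of 0.91 (camera adjusted p = 1.43e-15; adjusted p = 0.0774 with an estimated correlation). Inflammatory genes rose in 17 of 30 cases and fell in 2, or 18 and 2 adjusted over the list alone and 18 and 4 by DESeq2, with a median of 0.89, or 0.82 with 2 genes at their bound (camera adjusted p = 2.94e-07; adjusted p = 0.00233 with an estimated correlation). They included Ccl5 (2.34 ± 0.21), Ccl7 (1.97 ± 0.12) and Saa3 (1.42 ± 0.11). Cxcl5 had 66 counts in the siChst7 group and 11 in siControl (2.74 ± 0.44). Of 7 macrophage and leukocyte markers edgeR called 0, with 1 higher at an unadjusted p below 0.05 and 1 called by DESeq2, and the abundant members were Lyz2 at -0.04 ± 0.14, Cd68 at -0.12 ± 0.10 and Cd14 at -0.06 ± 0.09.

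The delivered factors fell together at day 3, Mef2c from 322 ± 3.43 to 249 ± 17.4 CPM (-0.37 ± 0.05), Gata4 with a log2FC of -0.36 ± 0.05 and Tbx5 with -0.33 ± 0.05 (camera adjusted p = 0.00428; adjusted p = 0.35 with an estimated correlation). The cardiac hormone genes rose, Nppa, whose 3' UTR holds GCGGCT, by 1.44 ± 0.16 and Nppb by 1.42 ± 0.12. Of 26 sarcomere genes 10 rose and 3 fell, or 10 and 4 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.117). Actc1 reached 199 ± 41.8 against 105 ± 8.74 CPM and Tnnc1 was at 1.05 ± 0.11, while Tpm1 did not pass (-0.04 ± 0.04). The pacemaker channel gene Hcn4 fell (-1.09 ± 0.22). Tagln was now higher with siChst7, at 467 ± 49.8 against 249 ± 5.5 CPM, and myofibroblast and TGF-beta genes numbered 9 higher and 6 lower of 25 (camera adjusted p = 0.13).

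Oxidative phosphorylation genes rose in 20 of 31 cases and fell in 6, or 21 and 7 adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.000199; adjusted p = 0.478 with an estimated correlation). Cox6c (1.27 ± 0.11), Cox7b (1.24 ± 0.10) and Ndufa4 (1.21 ± 0.11), short transcripts for respiratory chain subunits, were among the highest, and Sdha (0.00 ± 0.03) did not pass. Short transcripts as a class were higher in this comparison, with a rank correlation of -0.33 between length and log2FC across genes, against 0.05 at day 0 and -0.07 at day 1. Among random lists matched on gene length and mean expression, the interferon and inflammatory medians lay at percentile 100 and that of oxidative phosphorylation at 78.5. The cholesterol and delivered factor medians lay at 0.05 and 0.96. Those of the sarcomere list and of the myofibroblast and TGF-beta list, neither of which passed camera, lay at 98.2 and 99.4. The median of the glycosaminoglycan list, Chst7 among its genes, lay at 0.0, that of the matrix list at 19.5 and that of the fibroblast identity list at 82.3. Single genes were not matched on length, so the log2FC of short ones, such as Nppa and Nppb, and the counts of 2-fold changes may hold part of this trend. Of 27 genes of glycosaminoglycan sulfation and chondroitin synthesis, Chst7 among them, 14 fell and 3 rose, with a median of -0.22 (camera adjusted p = 0.000101; adjusted p = 0.218 with an estimated correlation). Without Chst7, 13 of the other 26 fell and 3 rose, with a median of -0.21 (camera adjusted p = 0.0134; adjusted p = 0.457 with an estimated correlation). They included the related sulfotransferases Chst12 (-0.50 ± 0.06) and Chst11 (-0.38 ± 0.05), and Papss2 (-0.36 ± 0.05), which makes the sulfate donor. Heparan sulfate genes numbered 7 lower and 1 higher of 14 (camera adjusted p = 0.13), with Ext1 at -0.41 ± 0.04, and proteoglycan core genes 7 lower and 2 higher of 22, or 11 and 2 by DESeq2 (camera adjusted p = 0.106). Cholesterol synthesis genes fell in 13 of 23 cases and rose in 3 (camera adjusted p = 0.0452; adjusted p = 0.538 with an estimated correlation), such as Srebf2 (-0.32 ± 0.05), a call lost without replicate 2 of siChst7 (camera adjusted p = 0.104) or replicate 2 of siControl (camera adjusted p = 0.0531). Matrix genes numbered 10 lower and 6 higher of 30, or 11 and 6 adjusted over the list alone and 15 and 6 by DESeq2 (camera adjusted p = 0.106), with Fn1 at -0.47 ± 0.05 and Sparc at -0.42 ± 0.04. Fibroblast identity genes numbered 6 higher and 6 lower of 27 (camera adjusted p = 0.781), Ly6a at 0.99 ± 0.14 among the higher.

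In all, edgeR called 6165 genes at day 3, or 44.7%, 3182 higher and 2983 lower, 395 and 25 by at least 2-fold. The share of higher genes, 51.6%, fell below that of lower ones with library totals (42%), DESeq2 size factors (42.5%) or upper quartile scaling (47.6%), with no filter (42.8%) or the stricter filter (42.2%), and without replicate 3 of siChst7 (41.1%). The groups did not overlap in 6777 genes (49.1%), where chance gives 10%. Leaving out replicate 1 or replicate 2 of siChst7 gave 5106 and 7124 called genes, and with both left out 5289 of the 6165 were called again, an alternative added after the data were seen.

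**Figure D3:**
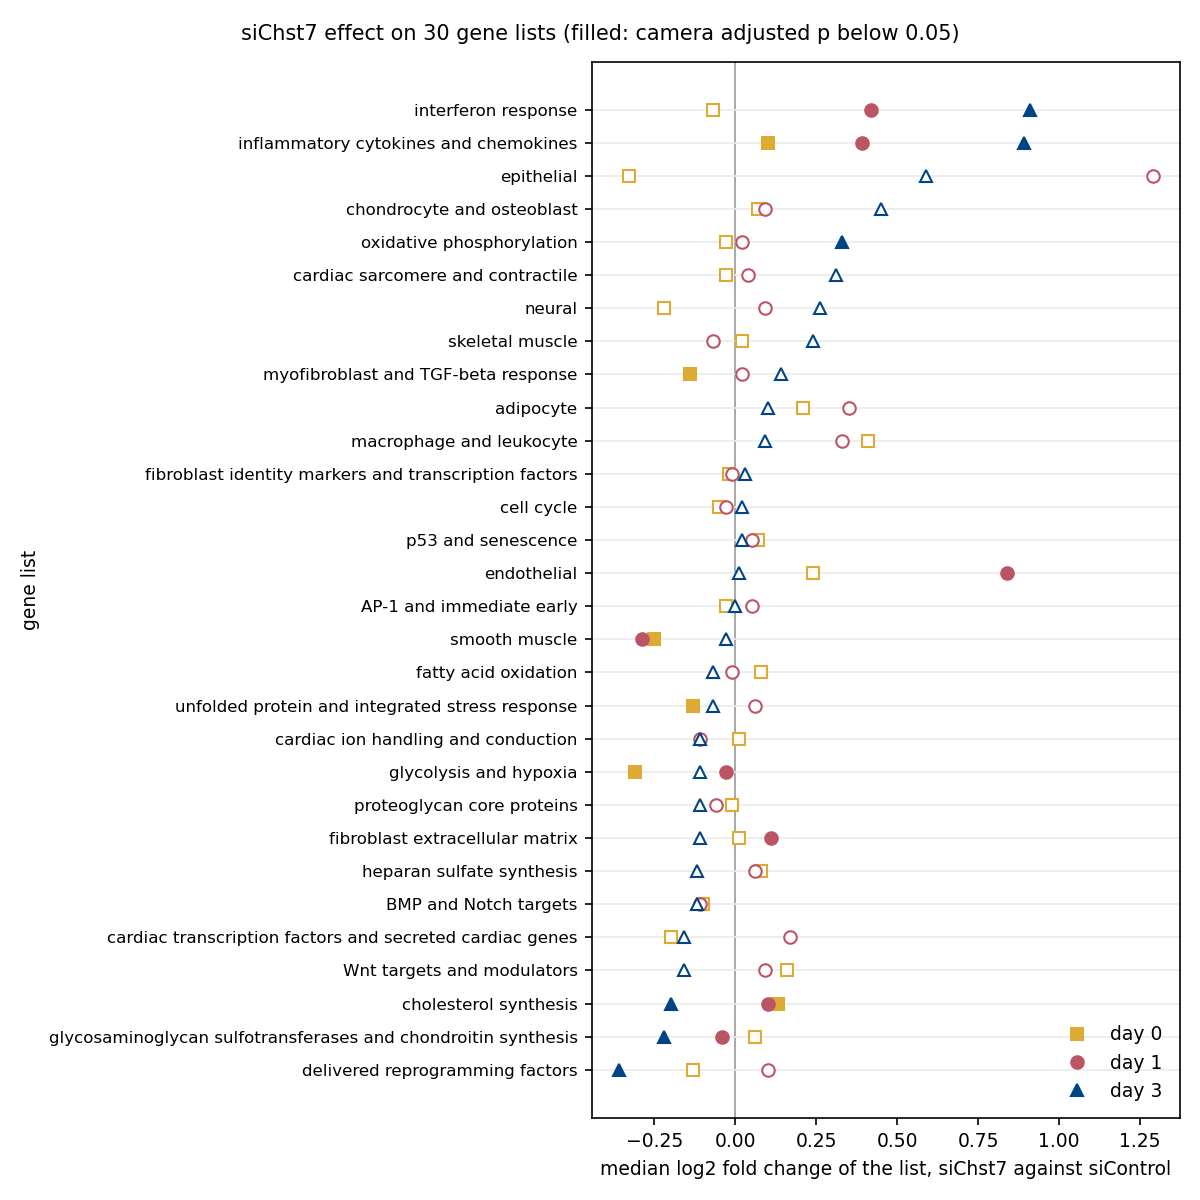
Median log2 fold change of each of 30 gene lists with siChst7 against siControl at days 0, 1 and 3, filled where the camera adjusted p was below 0.05. The interferon list moves from -0.07 at day 0 to 0.42 at day 1 and 0.91 at day 3.

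The siChst7 effect on the myofibroblast and inflammatory lists differed between days by the interaction term. That on the interferon list did so with the preset correlation alone (adjusted p = 0.0714 for day 1 and adjusted p = 0.0976 for day 3 with an estimated correlation). From day 0 to day 1 the effect on myofibroblast and TGF-beta genes rose in 14 of 25 cases and fell in 2, or 15 and 3 adjusted over the list alone, with a median of 0.35 (camera adjusted p = 4.8e-25; adjusted p = 0.00142 with an estimated correlation). For interferon genes it rose in 16 of 34 cases and fell in 0, or 23 and 0 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 7.98e-13; adjusted p = 0.0714 with an estimated correlation). Inflammatory genes, with 8 higher and 2 lower of 30 or 9 and 2 adjusted over the list alone (camera adjusted p = 7.41e-05), and stress response genes, with 12 higher and 0 lower of 28 (camera adjusted p = 2.35e-05), also passed with an estimated correlation (adjusted p = 0.0124 for each). Glycolysis and hypoxia genes had 7 higher and 0 lower of 26, or 13 and 1 adjusted over the list alone (camera adjusted p = 6.31e-06; adjusted p = 0.105 with an estimated correlation). Among single genes, the cytokine gene Tnfsf15 went from lower with siChst7 at day 0, at 0.95 against 2.33 CPM, to higher at day 1, at 21.5 against 8.25 CPM (interaction 2.67 ± 0.21, edgeR adjusted p = 1.48e-08). Ism1 went the other way (-1.65 ± 0.16, edgeR adjusted p = 4.13e-07). In all, edgeR called 1615 genes, 856 higher and 759 lower. With library totals as the only scaling the higher share was 30.2% in place of 53%, and with upper quartile scaling it was 46.4%.

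The interaction from day 0 to day 3 uses the same 6 day 0 libraries, so that the 2 interactions are not independent. The effect on myofibroblast and TGF-beta genes was higher at day 3 than at day 0 in 13 of 25 cases and lower in 5 (camera adjusted p = 8.6e-13; adjusted p = 0.029 with an estimated correlation). Interferon genes had 26 higher and 1 lower of 34, or 27 and 1 adjusted over the list alone, with a median of 0.97 (camera adjusted p = 8.6e-13; adjusted p = 0.0976 with an estimated correlation), and inflammatory genes 13 higher and 2 lower of 30, or 13 and 4 by DESeq2 (camera adjusted p = 0.00125; adjusted p = 0.0368 with an estimated correlation). Cholesterol synthesis genes had 13 lower and 1 higher of 23, or 15 and 1 adjusted over the list alone (camera adjusted p = 5.49e-05; adjusted p = 0.285 with an estimated correlation), and oxidative phosphorylation genes 18 higher and 5 lower of 31, or 18 and 6 adjusted over the list alone (camera adjusted p = 0.00127; adjusted p = 0.593 with an estimated correlation). Nppb went from 1.14 against 2.87 CPM at day 0 to 56 ± 11.5 against 20.9 ± 1.53 CPM at day 3 (interaction 2.76 ± 0.24, edgeR adjusted p = 2.38e-08). Jph2 rose relative to control (2.90 ± 0.43, edgeR adjusted p = 2.08e-05) and Ism1 fell (-1.87 ± 0.16, edgeR adjusted p = 3.11e-08). The interaction term called 5356 genes by edgeR in all, 2853 higher and 2503 lower. With library totals as the only scaling the higher share was 35.7% in place of 53.3%, and the median log2FC of all genes moved from 0.01 to -0.10. The higher share was also below that of lower genes with DESeq2 size factors (45.6%) or upper quartile scaling (47.1%) and with no filter (45.8%) or the stricter filter (45.6%). It was 45.7% with only the compared libraries and 45.2% without replicate 3 of siChst7 at day 3.

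Genes called with siChst7 at 2 of the days moved mostly the same way between days 0 and 1 and between days 1 and 3. For days 0 and 1, 530 genes were higher and 579 lower at both, where independent lists give 170 and 163, and 158 went opposite ways where 333 are given by chance (87.5% the same way). For days 1 and 3 the counts were 445 and 702, against 282 and 260, with 234 opposite against 542 (83.1%). For days 0 and 3 they were 335 and 691, against 442 and 404, with 874 opposite against 845 (54.0%). These comparisons share no library, and genes are not independent replicates. At all 3 days 168 genes were higher and 357 lower. Of these, chosen after their values were seen, the secreted phosphoprotein gene Spp1 had log2FC of 1.16, 1.40 and 1.81 at days 0, 1 and 3, and Mmp13 had 0.82, 1.26 and 1.14. Among the lower ones Pip4k2c had -1.16, -1.26 and -0.78, Prpf19 -1.08, -1.15 and -0.65 and the actin regulator Wdr1 -1.07, -0.71 and -0.58.

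Of 6 sets of genes that changed over time in siControl, 5 had a camera p below 0.05 with siChst7, in comparisons with no library in common. Some of these calls depended on the 2-fold limit, on the correlation used or on 1 library. The 979 genes that rose at least 2-fold by day 1 were lower with siChst7 at day 3 in 293 cases and higher in 134, with a median of -0.08 (camera p = 0.00152; p = 0.00519 with an estimated correlation). The 935 that fell were higher in 242 cases and lower in 99, with a median of 0.16 (camera p = 0.00625; p = 0.00509 with an estimated correlation), a call lost without replicate 2 of siChst7 at day 3 (camera p = 0.161) and without the 2-fold limit (camera p = 0.746). The 1298 genes that fell by day 3 were higher with siChst7 at day 1 in 242 cases and lower in 88, with a median of 0.08 (camera p = 0.000332; p = 0.00174 with an estimated correlation), a call lost without the 2-fold limit (camera p = 0.189 with the preset correlation). The 1725 that rose numbered 151 higher and 176 lower (camera p = 0.434; p = 0.247 with an estimated correlation). The 874 genes that rose from day 1 to day 3 were higher with siChst7 at day 0 in 154 cases and lower in 43, with a median of 0.24 (camera p = 0.00114; p = 0.000129 with an estimated correlation). For the 275 that fell, 58 were higher and 33 lower (camera p = 0.0305; p = 0.0687 with an estimated correlation), a call lost without replicate 3 of siChst7 at day 0 (camera p = 0.0689). Without the 2-fold limit that set turned to lower with siChst7 (camera p = 0.00117 with the preset correlation). Adjusted over these 6 tests, the 5 camera p below 0.05 became 0.00199 to 0.0366.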

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

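The tests of leukocyte markers and of a response to the siRNA duplex were chosen only after the results they bear on were seen.

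The siChst7 effect differed between days by the edgeR interaction term, in 1615 genes from day 0 to day 1 and in 5356 genes from day 0 to day 3. With the siRNA labels regrouped within days in 100 ways, the real one included, 1 grouping, the real one, reached each count, and the highest others were 887 and 2950. Such regrouping breaks the siRNA effect within each day along with its difference between days, so it does not exclude chance for the difference alone. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In each of them 1 split, the real one, reached its own count of 3785 (day 0), 2426 (day 1), 6165 (day 3), 8322 (siControl day 1) or 10132 (siControl day 3), and edgeR called 0 genes in the highest of the others, with up to 891, 537, 3667, 341 and 227 genes at an unadjusted p below 0.05. The 3667 at siChst7 day 3 come with the wide spread between the libraries of that group. Each of the other splits mixes libraries of both real groups. Real differences then widen the spread within the mixed groups and lower the counts, so these counts do not exclude chance.

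From day 0 to day 1 the median interaction was 0.35 for myofibroblast and TGF-beta genes, 0.46 for interferon genes, 0.30 for inflammatory genes (0.25 with 2 genes at their bound), 0.17 for glycolysis and hypoxia genes and 0.09 for unfolded protein and integrated stress genes, each called by camera. Of these the interferon and glycolysis calls were lost with an estimated correlation (adjusted p = 0.0714 and 0.105). It was 0.26, or 0.22 at the bounds, for cardiac transcription factors and secreted cardiac genes (camera adjusted p = 0.0134; adjusted p = 0.2 with an estimated correlation), a call lost without replicate 2 of siChst7 at day 0 (0.125), replicate 1 of siChst7 at day 1 (0.051) or the filter on low counts (0.215). It was 0.20 for AP-1 and immediate early genes (camera adjusted p = 0.0211; adjusted p = 0.387 with an estimated correlation), a call lost without either of the same libraries (0.0697 and 0.0833). It was -0.07 for fatty acid oxidation genes (camera adjusted p = 0.0464; adjusted p = 0.2 with an estimated correlation), a call lost without replicates 1 or 2 of siChst7 at day 0 (0.0851 and 0.104), replicates 2 or 3 of siChst7 at day 1 (0.065 and 0.07), replicate 2 of siControl at day 0 (0.0763), replicate 1 of siControl at day 1 (0.0842) or the filter on low counts (0.0504). From day 0 to day 3 the median was 0.24 for myofibroblast and TGF-beta genes, 0.97 for interferon genes, 0.56 for inflammatory genes, 0.39 for oxidative phosphorylation genes and -0.30 for cholesterol synthesis genes, each called by camera. Of these the interferon, oxidative phosphorylation and cholesterol calls were lost with an estimated correlation (adjusted p = 0.0976, 0.593 and 0.285). It was 0.21 for glycolysis and hypoxia genes (camera adjusted p = 0.0254; adjusted p = 0.51 with an estimated correlation), a call lost without replicate 2 of siChst7 at day 3 (0.28) and with library totals as the only scaling (0.0733). It was -0.15 for matrix genes (camera adjusted p = 0.0328; adjusted p = 0.599 with an estimated correlation), a call lost without replicate 3 of siChst7 at day 0 (0.132), replicate 2 of siControl at day 0 (0.0553) or replicates 1 or 3 of siControl at day 3 (0.0681 and 0.0617).

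Among single genes the interaction from day 0 to day 1 was 2.67 for Tnfsf15, 2.17 for Jph2, -1.65 for Ism1 and -1.78 for the peptide receptor partner Ramp3. It was 2.14 for Mustn1 (edgeR adjusted p = 0.018), a call lost without replicate 1 of siChst7 (0.0592) or of siControl (0.0618) at day 0, and -1.76 for Csdc2 (edgeR adjusted p = 0.00593), a call lost without replicate 3 of siChst7 at day 0 (0.0585). From day 0 to day 3 it was 2.90 for Jph2, 2.76 for Nppb, 2.69 for Ccdc68, -1.87 for Ism1 and -1.97 for Csdc2. Jph2 had 51 counts in siControl and 8 with siChst7 at day 0. Afap1l2, with 2 and 14 counts at day 0, had -2.76 (edgeR adjusted p = 0.0241), a call lost without replicate 2 of siChst7 (0.269) or replicates 1 or 3 of siControl (0.0779 and 0.0837) at day 0, and a value that moved to -5.31 without replicate 2 of siControl. Mybph, with 0 counts in siControl and 11 with siChst7 at day 0, had fitted values of -4.79 and -4.50 for the 2 interactions, and Xirp2, with 8 and 0 counts and GCGGCT in its 3' UTR, had 5.05 and 4.35. Such values depend on the prior count and are no bounds. The Xirp2 calls were lost without replicate 1, 2 or 3 of siChst7 at day 0 (edgeR adjusted p = 0.0725, 0.0617 and 0.0631 for day 1 and 0.063, 0.0551 and 0.0586 for day 3) and without replicate 1 of siControl at day 0 (0.204 and 0.16).

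Interferon and inflammatory genes were higher with siChst7 at days 1 and 3 by camera, the interferon calls being lost with an estimated correlation (adjusted p = 0.107 and 0.0774). For the interferon genes, the median of -0.07 at day 0 argues against a stronger response to siChst7 than to the control siRNA 1 day after transfection. Both groups were transfected, so a response common to both siRNAs would cancel in this comparison and cannot be excluded by it. A lag common to all genes that fell over time in siControl is argued against by the position of both lists at both days. They lay at the 99.7th percentile or above among random lists matched on the change in siControl and on mean expression. How far the random lists themselves fell was not checked, and the genes with the steepest falls may have had no close match. A lag particular to such genes therefore cannot be told apart. Leukocytes among the siChst7 cells are argued against at day 3, where 0 of 7 leukocyte markers were called by edgeR (1 higher at an unadjusted p below 0.05, and 1 called by DESeq2) and the abundant Lyz2, Cd14 and Cd68 lay at -0.04, -0.06 and -0.12. At day 1, where 3 of the 7 were called, leukocytes cannot be told apart from fibroblasts that express such genes, because Lyz2 was at -0.15 and Cd14 at 0.37. A response that arises only after day 0, other targets of the siRNA and the loss of Chst7 itself stay open. So does a response common to both siRNAs at day 0 that differs between them later. An early response to the duplex also stays open for the inflammatory genes, which were called higher at day 0 too (camera adjusted p = 0.0375, and 0.104 with an estimated correlation).

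Oxidative phosphorylation genes were higher with siChst7 at day 3 by camera (adjusted p = 0.478 with an estimated correlation), where siChst7 libraries also had relatively more reads on short genes. Among random lists matched on gene length and mean expression, the median of the list (0.33) lay at the 78.5th percentile, so that a length bias between libraries, from RNA quality or library preparation, is a candidate explanation. Neither library that stood apart in this group accounts for it alone, since the median was 0.28 without replicate 1, which had the highest Rn45s share, and 0.45 without replicate 2. A biological rise of short transcripts of nuclear genes for respiratory chain subunits stays open as untested.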

How the results depend on the processing

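The removal of both replicates 1 and 2 of siChst7 at day 3, and of Chst7 from its own list, was chosen only after the data were seen. All other alternatives were planned. Counts of called genes stayed within 1.5 times of the reported ones under the other scalings, filters and the DESeq2 test. An adjusted p of 0.01 gave 2481 genes at day 0, 1436 at day 1 and 847 for the interaction with day 1, and same-direction overlaps of 653 (days 0 and 1), 598 (days 0 and 3) and 645 (days 1 and 3). A test against a fold change of 1.2, which asks for larger changes, gave 846 (day 0), 368 (day 1), 1689 (day 3, 80.3% higher), 4925 (siControl day 1), 378 and 2189 (interactions with days 1 and 3). With only the compared libraries in the fit, day 1 gave 3924 genes and its interaction 2448. Under the same setting 4640 of the 6165 genes of siChst7 at day 3 and 4757 of the 5356 of its interaction were called again. The fit of all libraries pools the estimate of spread over groups, and siChst7 at day 3 had the widest spread, so its calls depend on that pooling. The cause of these shifts was not tested. The number of lists called with an estimated correlation was 2, 2 and 1 for siChst7 at days 0, 1 and 3, 6 for siControl at day 1, and 3 and 2 for the interactions. Fry, which makes no comparison with other genes, called 18, 16 and 22 lists for siChst7, 29 and 24 for siControl at days 1 and 3, and 13 and 19 for the interactions. Without a filter the interaction with day 3 had 11 lists.

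Of the sets of genes that changed over time in siControl, those that fell lost their calls when the 2-fold limit was dropped, for day 1 in siChst7 at day 3 (camera p = 0.746 with the preset correlation) and for day 3 in siChst7 at day 1 (0.189). The set that fell from day 1 to day 3 turned from higher to lower in siChst7 at day 0 (0.00117) without that limit, and had p = 0.0687 with an estimated correlation. The cause was not tested.

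Leaving out 1 library at a time gave 2952 to 3375 genes at day 0, 1805 to 1917 at day 1, 5106 to 7124 at day 3, 7772 to 7835 and 9664 to 9732 for siControl at days 1 and 3, and 1219 to 1465 and 4797 to 6503 for the interactions. Lists called ranged from 5 (without replicate 2 of siChst7 at day 0) to 10 for the interaction with day 1. For the sets that fell, camera p ranged from 0.00137 to 0.161 (highest without replicate 2 of siChst7 at day 3) and from 0.0278 to 0.0689 (highest without replicate 3 of siChst7 at day 0).

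The labels give the groups the same replicate numbers. Correlations between samples with a number in common ran from -0.066 to 0.068, with a mean of -0.001 against 0.001 for other pairs. Still, 10 of 18 libraries were closest to their own number, more than an even spread over the 3 numbers would give. A weak pairing is therefore not excluded. With the replicate number as a block, 3601 of 3785, 2260 of 2426 and 5975 of 6165 genes called with siChst7 at days 0, 1 and 3 were called again, and 1463 of 1615 and 5165 of 5356 for the interactions. None of the counts reported here moved by more than 1.5 times under the block.

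Depth limits genes near the floor. Calls such as those of Xirp2, Mybph and Afap1l2 rest on groups with 0 to 14 counts at day 0, while Chst7 had 840 to 861 counts in each siControl library of that day. The lowest total, 30590742 counts, was that of replicate 3 of siChst7 at day 3, the group with the widest spread between replicates. Without replicates 1 and 2 of that group, which leaves 1 library assumed to vary like the other groups, 5289 of the 6165 genes at day 3 and 4884 of the 5356 of its interaction were called again, the cholesterol list at day 3 had camera adjusted p = 0.0893 and the glycolysis list of the interaction 0.243.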

Other observations

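The test of short words in 3' UTRs was chosen only after the result was seen.

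Over the time course of siControl cells, Wnt and Notch pathway genes moved both ways. Axin2, a feedback gene of Wnt signalling, rose by 3.33 ± 0.06 at day 1 and 2.49 ± 0.06 at day 3 on the log2 scale, while the secreted Wnt inhibitor gene Sfrp1 was at -2.26 ± 0.04 and -2.59 ± 0.04. Of 16 Wnt genes 3 rose and 9 fell at day 1, or 3 and 10 adjusted over the list alone (camera adjusted p = 0.122), and 5 rose and 7 fell at day 3 (camera adjusted p = 0.833), where the median of -0.23, mean of 0.81 and downward test differed in sign. Of 18 BMP and Notch genes 10 rose and 5 fell by day 3 (camera adjusted p = 0.487), from the receptor gene Notch3 at 2.98 ± 0.08 to the BMP target Id1 at -2.05 ± 0.08. Skeletal muscle markers rose in 8 of 11 cases and fell in 1 by day 3 (camera adjusted p = 0.0539), with the actin gene Acta1 at 2.39 ± 0.10 and Myog, which had 0 counts at day 0, at least 30.7-fold higher. Of 10 cartilage and bone markers 4 rose and 3 fell by day 3 (camera adjusted p = 0.804, with a median of 0.07 and a downward test), with Col2a1 at 4.29 ± 0.34 and Sox9 at -2.64 ± 0.14. Genes of glycosaminoglycan sulfation and chondroitin synthesis were divided at day 3, with 11 higher and 11 lower of 27 (camera adjusted p = 0.833, with a median of -0.10 and an upward test), and the sulfotransferase gene Chst3 was at 3.24 ± 0.11. Endothelial markers numbered 2 higher and 3 lower of 7 (camera adjusted p = 0.933, with a median of 0.37 and a downward test), neural markers 2 higher and 0 lower of 8 (camera adjusted p = 0.693) and epithelial markers 0 higher and 1 lower of 5 (camera adjusted p = 0.933). Macrophage and leukocyte markers were not called as a list by camera at day 3, but of these 7 genes DESeq2 called 5 lower and 2 higher, with a median log2FC of -1.24.

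With siChst7, Wnt genes rose in 6 of 16 cases and fell in 2 at day 0 (camera adjusted p = 0.282), Notum by 0.52 ± 0.07 among them, and at day 3 they fell in 3 cases and rose in 0, or 6 and 0 by DESeq2 (camera adjusted p = 0.13), with Axin2 at -0.37 ± 0.06. Of 18 BMP and Notch genes 3 rose and 3 fell at day 0, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.54), with the BMP antagonist gene Grem1 at 0.59 ± 0.04 and the Notch ligand gene Jag1 at -1.01 ± 0.07. Of 24 p53 and senescence genes 6 rose and 2 fell at day 0, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.132), with Trp53inp1 at 1.21 ± 0.08. At day 3 cell cycle genes numbered 12 higher and 6 lower of 34, or 12 and 7 adjusted over the list alone (camera adjusted p = 0.238), with Ccne2 at 0.78 ± 0.09, and fatty acid oxidation genes 5 higher and 10 lower of 23, or 6 and 11 adjusted over the list alone and 3 and 11 by DESeq2 (camera adjusted p = 0.163), with Acaa2 at -0.51 ± 0.05. Adipocyte markers rose in 3 of 6 cases and fell in 0 at day 0, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.282), with Plin4 at 0.85 ± 0.15.

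Genes lower with siChst7 held 1 particular word in the 3' UTR more often than other genes, though most of them lacked it. Of all 4096 words of 6 bases, GCGGCT was the one most tied to lower expression at day 0 (adjusted shift -0.086, z = -6.3). It ranked 1 again at day 1 (-0.094, z = -7.5) and 76 at day 3 (-0.041, z = -3.1), and the Chst7 transcript holds it 2 times. These shifts are adjusted for the length and the G and C share of the 3' UTR. Base composition in place of 1 word is argued against, since the lowest z at day 1 among 47 words with the same bases and a CG was -4.7 (TGCGGC). The word was in 29.8% (95% Wilson interval 25.3 to 34.8%) of the genes lower at all 3 days, in 1.88% of those higher at all 3 days and in 8.32% of all genes with a 3' UTR. It was chosen by its day 0 values, which these groups also use, so their contrast was partly fixed in advance. In groups that use no day 0 call, it was in 23.9% of genes lower at days 1 and 3 and in 3.58% of those higher. Matches to this word thus do not account for most of the shared decreases. A candidate explanation for part of them is repression by the seed of 1 siRNA strand, a known off-target effect, but the siRNA sequences are not given in the sources used here and siRNA with another seed was not analysed here.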
